A study of Mus musculus with 3 samples.

How the data were processed

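RNA from dissected cerebella of C57Bl/6 mice at postnatal day 10 was compared on 3 arrays with 2 colours each. Per the labels, every array held wild-type RNA in channel 1 and RNA of a Smarca5 conditional knockout (cKO) in channel 2. The cKO was labelled with Cy5 on replicates 1 and 2 and with Cy3 on replicate 3, the dye-flipped array. Per the labels' protocols, RNA was isolated with Trizol and the cDNA was labelled with a Genisphere dendrimer kit. The series text gives 3 samples of each strain, without stating whether these were separate animals or pools. All p-values therefore measure the spread between these arrays, which may be technical.

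The deposited table holds 1 centred log ratio per probe and array for 38880 probes, and its values were used as log2 ratios. The authors' scanner software, background correction and normalization are not given in the sources used here. The log base is not stated either. A log10 scale was ruled out because the largest values exceed what the ratio of a pair of scanner readings can reach on that scale, but a natural log was not ruled out. Fold changes below hold only if the base is 2. The mean and the median of each array were 0, so the values are relative to the average probe of an array. No intensities were used here, so signal over background is unknown, no filter on dim probes was run and no bound was set for dim probes. The number of arrays limits the precision.

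The direction of the ratios was set from the labels and from the spots. Values were read as channel 2 over channel 1, that is cKO over wild type, on every array. A set of 47 unnamed spots, each the first of a run of 810 probes in 47 of the 48 runs, carried values over 5 in size. Their mean was -7.86 on replicate 1, -7.93 on replicate 2 and 7.71 on replicate 3. Spots that follow the dye and not the sample turn their sign on a dye-flipped array when all ratios run channel against channel, which set the arrays' orientation relative to each other. Over all spots, replicate 3 had a Pearson's r of 0.0566 with replicate 1 and 0.0384 with replicate 2, not below the negative bound set in advance for turning its sign. Which channel is the numerator rests on the labels and on the lower value of Smarca5 in the direction chosen. After these 47 spots were left out, Pearson's r across probes was 0.443 between replicates 1 and 2, 0.266 between replicates 1 and 3, and 0.223 between replicates 2 and 3. Probes are not independent replicates. A further 5 spots with the same sign pattern stayed in the fit.

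Probes were named from the platform annotation, which is old. Of the 38880 probes, 30457 had 1 gene symbol, 0 had several and 8423 had none and are unnamed here. Symbols were updated through a RefSeq gene table of another build, which served for names and for the order of neighbouring genes. A current symbol was matched by 19043 probes and a synonym of 1 gene by 11114. The array's own symbol was kept for 300 probes whose symbol is a synonym of several genes. Probes of 1 gene were averaged on each array before the fit, which concerned 6691 genes, and unnamed probes stayed single. Features measured on all 3 arrays were kept, which gave 19855 named genes and 8341 unnamed probes, 28196 features in all.

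The log ratios were tested against 0 with limma (lmFit with an intercept and eBayes, moderated statistic), adjusted by the Benjamini-Hochberg method over all features at a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 2.08. Gene lists of at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists tested. Beside it stand camera with a correlation estimated from the arrays and fry, which tests whether the genes of a list move on balance one way. Members of a list were also adjusted over the list alone. Errors are standard deviations over the 3 arrays. The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

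The test, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named Smarca5 and 12 further fixed genes, the 10 genes of smallest p in each direction among those with the same sign on all 3 arrays, and of each list the 2 members of smallest p, since no gene passed the threshold. Predicted genes and clone names, judged by the updated symbol, were left out of the 10 in each direction. By their symbols on the array, C1ql2, Agpat5, Mrln, Trmt9b, Smarca5-ps and Sult6b1 would have been left out too. They entered through the symbol update, so this part of the rule was not fully fixed before the data were seen. Members of lists named beyond this rule were picked after their values were seen. Leaving out the 47 marker spots, the update of symbols through synonyms, lists without their most changed member and lists without Smarca5 were decided after the data had been seen.

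The alternatives tried were centring or scaling of each array, the sign of replicate 3 turned, a dye term, array weights, a robust prior, each probe tested on its own, features measured on at least 2 arrays, probes with an exact 0 left out, each replicate left out, a one-sample test without moderation, adjusted p under 0.1, a minimum of 1.5-fold, an estimated correlation, and fry. Symbols as on the array, the marker spots kept, lists without their most changed member and lists without Smarca5 were tried as well. Centring and scaling left the median of all features at 0.003 and 0.00237, against 0.003 as deposited. The procedure was tested on simulated data with 28196 features and the spread of these arrays, drawn independently for each gene. At adjusted p under 0.05 it recovered 0 of 50 genes changed by 0.5 on the log2 scale, 0 of 50 changed by 1, 7 of 50 changed by 2 and 35 of 50 changed by 3. No other simulated genes were changed, whereas 2219 real features had an unadjusted p under 0.01 in limma against 282 by chance. Recovery after this adjustment depends on the number of changed genes, so these rates need not hold for the real arrays. Among unchanged simulated genes, 0.918% had an unadjusted p under 0.01. A simulated list of 15 genes shifted by 1 had an adjusted p of 9.47e-21 with the preset correlation and 0.643 with an estimated correlation. Only that list was shifted, and the simulated genes were uncorrelated.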

Results

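The arrays measured RNA of the cerebellum at postnatal day 10 in mice with a conditional knockout (cKO) of Smarca5 and in wild-type controls. Smarca5, also called Snf2h, encodes the ATPase of the ISWI family of chromatin remodelers, which slide and space nucleosomes. Each of 3 arrays held 1 cKO and 1 wild-type sample, so each array gave 1 ratio of cKO over wild type per gene. The comparison asks which genes differ in expression between the mutant and the normal cerebellum while granule neurons are still being produced. A total of 19855 named genes and 8341 unnamed probes had a value on all 3 arrays. Values are log2 ratios of cKO over wild type, with the SD over the arrays (n = 3); below 0 means lower in the cKO.

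Smarca5 itself was lower in the cKO on every array, with a mean of -0.86 ± 0.11 (SD, n = 3), which is 0.552 of the wild-type level. Its values were -0.75, -0.96 and -0.88 on replicates 1, 2 and 3. The adjusted p of 0.0885 (limma's moderated statistic, Benjamini-Hochberg) missed the threshold of 0.05. Its 2 probes differed in size, with a mean of -1.28 ± 0.15 for the probe annotated as Smarca5 and -0.44 ± 0.26 for a probe annotated as a clone. A further probe, also a clone on the array and named the pseudogene Smarca5-ps only by the symbol update, had -1.81 ± 0.06. The pseudogene's sequence is close to that of Smarca5, so which of the pair the probe measured is uncertain. Whether the probes lie inside the deleted part of the gene is not known here, and the direction of the ratios rests partly on Smarca5 being lower, so its sign is no independent check of the labels. Smarca1, which encodes the other ISWI ATPase, had 0.23 ± 0.42, with values from -0.21 to 0.62.

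Genes of granule neurons, the most numerous neurons of the cerebellum, were lower in the cKO, and genes of microglia were higher. Gene lists of granule cell progenitors and of the cell cycle were also lower, while lists of the interferon response, the oligodendrocyte lineage, the choroid plexus, the meninges, and brainstem and midbrain neurons were higher. Lists of Purkinje cells, astrocytes and endothelium had means near 0. Lists of SNF2-type remodelers and of synaptic genes were slightly lower. In all, 11 of 22 lists passed camera at adjusted p under 0.05 with the preset correlation, and 0 of 22 passed with a correlation estimated from the arrays. Before adjustment, camera with an estimated correlation gave these 11 lists p from 0.0166 (microglia) to 0.161 (synaptic genes). No single gene passed limma's adjusted p of 0.05 over all 28196 features, of which 5893 had an unadjusted p under 0.05.

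**Figure D1:**
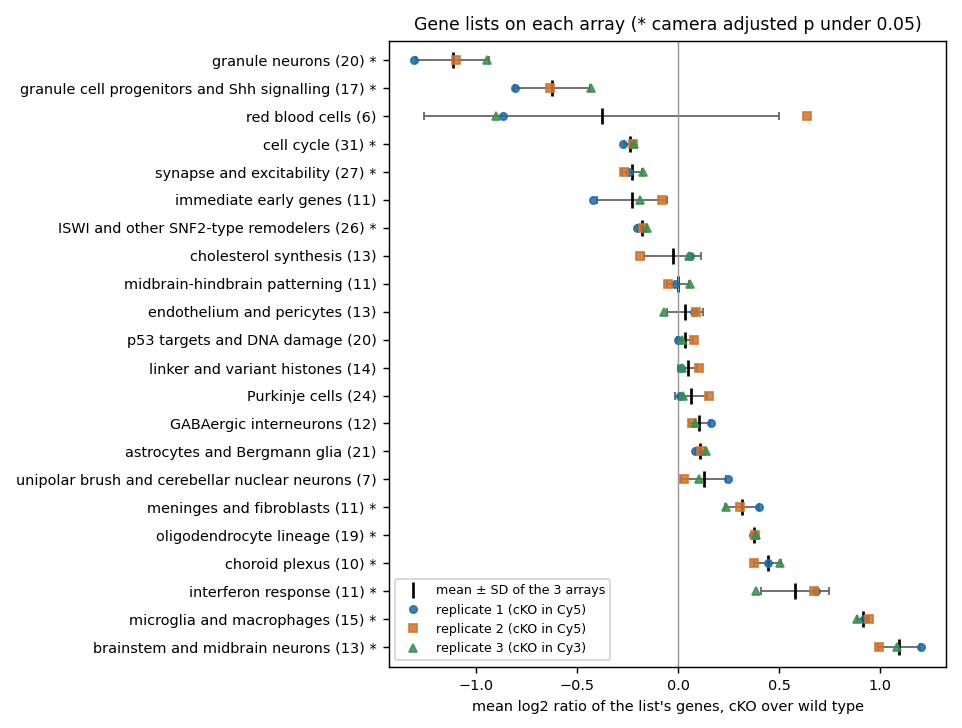
Mean log2 ratio (cKO over wild type) of the genes of each list on each of the 3 arrays, with the mean and SD over the arrays; numbers in parentheses are measured genes and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Granule neurons lie lowest, with means from -1.31 to -0.95 on the arrays, and brainstem and midbrain neurons lie highest.

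The granule neuron list fell, with a mean of -1.12 ± 0.18 over 20 measured genes (limma's camera, adjusted p = 2.18e-13; adjusted p = 0.232 with an estimated correlation). Of the 20 genes, 19 were lower on all 3 arrays and 19 were lower adjusted over the list alone, the exception being Cntn1 at 0.15 ± 0.09. The lowest was Gabrd, the delta subunit of extrasynaptic GABA-A receptors, at -2.50 ± 0.36, followed by Pax6 at -2.13 ± 0.47, a transcription factor of the granule lineage. Etv1, a transcription factor of maturing granule cells, had -1.96 ± 0.18, which is 3.89-fold lower, and its 3 probes were all lower. Gabra6, the GABA-A subunit that marks mature granule neurons, had -1.34 ± 0.58 and was less far below 0 on the dye-flipped array (-0.67) than on the others (-1.68 on both). Neurod1, which drives granule cell differentiation, had -0.51 ± 0.26.

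The list of granule cell progenitors and Sonic hedgehog signalling fell as well, with a mean of -0.62 ± 0.19 over 17 genes (limma's camera, adjusted p = 0.00337; adjusted p = 0.232 with an estimated correlation). Its members Atoh1, Barhl1, Boc, Insm1 and Nhlh1 were lower adjusted over the list alone, 5 of 17, and 12 did not pass. Atoh1, the transcription factor that specifies the granule lineage, had -1.88 ± 0.45, and Nhlh1, expressed in early differentiating granule cells, had -2.54 ± 0.34. Hedgehog targets did not pass over the list alone. Ptch1 had -0.84 ± 1.31 and changed sign on the dye-flipped array, with 0.64 there against -1.88 and -1.28 on the others. Ccnd1 had -0.38 ± 0.37, with 0.04 there against -0.53 and -0.64, while Gli2 had 0.10 ± 0.25 and Mycn -0.38 ± 0.16. Hhip was above 0 on all 3 arrays, at 0.23 ± 0.21.

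The cell cycle list fell by less, with a mean of -0.24 ± 0.03 over 31 genes (limma's camera, adjusted p = 0.00473; adjusted p = 0.232 with an estimated correlation). Of its genes, 21 were below 0 and 15 of these on all 3 arrays, but 0 passed adjusted over the list alone. The smallest p belonged to E2f1, a transcription factor of S phase entry, at -1.17 ± 0.29, and to Mcm5, a subunit of the replicative helicase, at -0.91 ± 0.29. Mki67, the proliferation marker Ki-67, had -0.15 ± 0.14, and its 4 probes differed in sign.

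The microglia and macrophage list rose, with a mean of 0.92 ± 0.03 over 15 genes (limma's camera, adjusted p = 8.29e-12; adjusted p = 0.232 with an estimated correlation). All 15 were above 0 on all 3 arrays, and 14 were higher adjusted over the list alone, the exception being Itgam at 0.33 ± 0.26. Aif1, which encodes the microglial protein Iba1, had 1.23 ± 0.19 and Fcer1g, an adaptor of Fc receptors, had 1.17 ± 0.11. The complement genes C1qa, C1qb and C1qc had 0.93 ± 0.24, 0.81 ± 0.24 and 1.00 ± 0.22. P2ry12, a marker of resting microglia, had 0.84 ± 0.12.

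The interferon response list rose with a mean of 0.58 ± 0.17 over 11 genes (limma's camera, adjusted p = 1.99e-04; adjusted p = 0.232 with an estimated correlation). Of these, 6 were higher adjusted over the list alone and 5 did not pass. Ifit3, an antiviral gene induced by interferon, had 1.01 ± 0.09, and Bst2 had 0.61 ± 0.11. The 3 probes of Ifit3 had 0.97 ± 0.46, 1.42 ± 0.17 and 0.65 ± 0.61, so each spread more than their average. Rsad2, another interferon target, had -0.09 ± 0.43.

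The oligodendrocyte lineage list rose with a mean of 0.38 ± 0.01 over 19 genes and a median of 0.15 (limma's camera, adjusted p = 0.00186; adjusted p = 0.232 with an estimated correlation). The 7 genes higher adjusted over the list alone were Bcas1, Enpp6, Ermn, Olig2, Opalin, Pdgfra and Sox10. Opalin had 1.20 ± 0.17, Enpp6, a marker of newly formed oligodendrocytes, had 1.02 ± 0.15, and Pdgfra, the growth factor receptor of their precursors, had 1.01 ± 0.15. Cspg4, another gene of these precursors, was below 0 on all 3 arrays at -0.30 ± 0.17 and did not pass. Among genes of myelin proteins that did not pass, Mbp had 0.04 ± 0.05, Mag 0.04 ± 0.07 and Mog, below 0 on all 3 arrays, -0.21 ± 0.09. The list of astrocytes and Bergmann glia was not called, with a mean of 0.11 ± 0.03 over 21 genes (adjusted p = 0.247 with limma's camera) and 0 members passing over the list alone. Gfap, the intermediate filament of astrocytes, had 0.46 ± 0.14, Hes5 0.67 ± 0.25 and Gdf10, a marker of Bergmann glia, -0.69 ± 0.17. The 2 probes of Gdf10 differed in size, at -0.18 ± 0.06 and -1.19 ± 0.35.

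**Figure D2:**
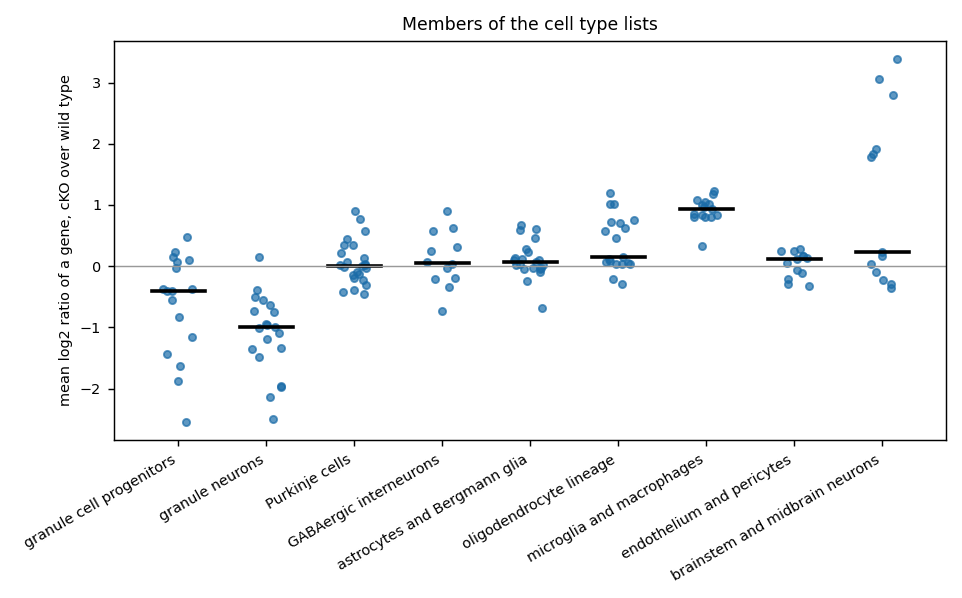
Mean log2 ratio (cKO over wild type) over the 3 arrays of each measured gene in 9 cell type lists, with the black bar at the median of the list. Microglial genes form a narrow group around a median of 0.93, whereas in the brainstem and midbrain list 6 genes lie at 1.78 or above and the others between -0.35 and 0.23.

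The list of brainstem and midbrain neurons rose, with a mean of 1.09 ± 0.10 and a median of 0.23 over 13 genes (limma's camera, adjusted p = 0.00473; adjusted p = 0.232 with an estimated correlation). The 6 members higher over the list alone were 5 genes of dopamine and serotonin neurons and 1 gene of acetylcholine neurons. Ddc, an enzyme of dopamine and serotonin synthesis, had 1.83 ± 0.13 and Slc18a3, the vesicular acetylcholine transporter, had 1.78 ± 0.40. Chat, the enzyme of acetylcholine synthesis, did not pass over the list alone at 0.23 ± 0.14. The dopamine transporter gene Slc6a3 had 3.39 ± 1.71, the serotonin transporter gene Slc6a4 3.06 ± 1.18, Tph2 2.80 ± 1.22 and Th 1.91 ± 0.72. Replicate 2 stood apart in opposite directions for these genes. Slc6a3 had 1.43 there against 4.55 and 4.18 on replicates 1 and 3, and Th 1.09 against 2.41 and 2.23. The serotonin genes were highest on it, Slc6a4 with 4.32 against 2.90 and 1.97 and Tph2 with 4.07 against 2.69 and 1.63. The Hox genes of the list, which mark the hindbrain behind the cerebellum, ranged from -0.35 ± 0.72 (Hoxb2) to 0.17 ± 0.27 (Hoxa5). This rise stood in the same arrays as the lower granule and the higher microglial and oligodendrocyte lists.

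Lists of tissue bordering the cerebellum differed as well. The choroid plexus list rose with a mean of 0.44 ± 0.07 over 10 genes (limma's camera, adjusted p = 0.00245; adjusted p = 0.232 with an estimated correlation). Adjusted over the list alone, 7 members were higher, among them Clic6 at 0.65 ± 0.11 and Calml4 at 0.65 ± 0.13, and Otx2 was lower at -0.45 ± 0.11. Ttr, the most abundant choroid plexus transcript, had 0.02 ± 0.03. The list of meninges and fibroblasts rose with a mean of 0.31 ± 0.08 over 11 genes (limma's camera, adjusted p = 0.00473; adjusted p = 0.232 with an estimated correlation), and 0 members passed over the list alone. Its members of smallest p were Igfbp2 at 0.73 ± 0.25 and Foxc1 at 0.58 ± 0.20. The list of endothelium and pericytes was not called, with a mean of 0.03 ± 0.09 over 13 genes (adjusted p = 0.815 with limma's camera), and its genes of smallest p were Esam at -0.30 ± 0.10 and Slco1a4 at 0.29 ± 0.31. The list of red blood cells had a mean of -0.38 ± 0.88 over 6 genes and was not called (adjusted p = 0.247 with limma's camera). Replicate 2 stood apart there at 0.64, against -0.87 and -0.91 on replicates 1 and 3, and without replicate 2 the list was called at -0.89 (limma's camera, adjusted p = 0.00196). Hbb-y, an embryonic globin, had -1.02 ± 0.96 and Alas2, an enzyme of haem synthesis in red cells, had -0.78 ± 1.78.

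Purkinje cells, the output neurons of the cerebellar cortex, had a list mean of 0.06 ± 0.08 over 24 genes, which was not called (adjusted p = 0.85 with limma's camera). Adjusted over the list alone, Aldoc at 0.90 ± 0.16 and Nefh at 0.76 ± 0.06 were higher and 22 genes did not pass. Calb1, the calcium buffer that marks these cells, had 0.01 ± 0.24. Pcp2, a Purkinje cell marker, had -0.23 ± 0.62, with 0.49 on the dye-flipped array against -0.59 and -0.58 on the others. The GABAergic interneuron list had a mean of 0.10 ± 0.05 over 12 genes (adjusted p = 0.78 with limma's camera). Over the list alone Gad2, an enzyme of GABA synthesis, was higher at 0.90 ± 0.14 and Tfap2a was lower at -0.74 ± 0.14. The list of unipolar brush and cerebellar nuclear neurons had a mean of 0.12 ± 0.11 over 7 genes and was not called (adjusted p = 0.389 with limma's camera). Adjusted over the list alone, Lhx9 (0.75 ± 0.02), Irx3 and Lmx1a were higher, whereas Tbr1 (-1.10 ± 0.39) and Eomes (-0.79 ± 0.27), transcription factors of these excitatory neurons, were lower.

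The midbrain-hindbrain patterning list went both ways, with a mean of -0.0035 ± 0.05 over 11 genes (adjusted p = 0.815 with limma's camera). En2, a homeobox gene of the cerebellar primordium, was lower over the list alone at -1.49 ± 0.17, which is 2.8-fold lower. Its paralog En1 was higher over the list alone at 0.57 ± 0.06, as were Pax8 at 1.34 ± 0.38 and Irx5 at 0.76 ± 0.35. In fry the list moved on balance downward (adjusted p = 0.0335 from limma), which does not compare it with other genes.

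The list of ISWI and other SNF2-type remodelers fell slightly, with a mean of -0.18 ± 0.02 over 26 genes (limma's camera, adjusted p = 0.0323; adjusted p = 0.251 with an estimated correlation). No member passed over the list alone; Smarca5 and Chd5, the latter at 0.87 ± 0.23, had the smallest p. The list holds the targeted gene itself, and without Smarca5 its mean was -0.15 and the call was lost (adjusted p = 0.0719 in limma's camera). Without Chd7, its most changed member at -1.07 ± 0.42, the list had an adjusted p of 0.0714 in limma's camera. The call was also lost with a dye term (adjusted p = 0.0519), with each probe tested on its own (0.124), without replicate 1 (0.111) and with symbols as on the array (0.125). The synapse and excitability list fell by 0.23 ± 0.05 over 27 genes, with a median of -0.03 (limma's camera, adjusted p = 0.0323; adjusted p = 0.323 with an estimated correlation). Adjusted over the list alone, 8 genes were lower, among them the AMPA receptor subunit Gria4 (-1.18 ± 0.16) and the potassium channel Kcnc1 (-1.05 ± 0.06), and Scn1a (0.55 ± 0.09) and Vamp1 (0.75 ± 0.08) were higher. This call was lost with a dye term (adjusted p = 0.0567), each probe tested on its own (0.0734), symbols as on the array (0.212), without the most changed member (0.0786), without moderation (0.0892), without replicate 1 (0.0729) and without replicate 2 (0.0531).

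The remaining lists were not called. Linker and variant histones had a mean of 0.05 ± 0.05 over 14 genes, while their median was -0.05 and camera's direction was down (adjusted p = 0.92 from limma), so these differ in sign. The linker histone genes H1f2 and H1f5 had 0.86 ± 0.26 and 0.60 ± 0.22, and 0 members passed over the list alone. Immediate early genes had a mean of -0.23 ± 0.18 over 11 genes (adjusted p = 0.389 with limma's camera), with Dusp1 at -0.99 ± 0.40 and Arc at 0.40 ± 0.14. Targets of p53 had a mean of 0.03 ± 0.04 over 20 genes (adjusted p = 0.815 with limma's camera). Over the list alone Phlda3, an inhibitor of Akt, was higher at 1.14 ± 0.12 and Bbc3, which encodes the apoptosis inducer Puma, was lower at -0.89 ± 0.07. Cdkn1a, the cell cycle inhibitor p21, had -0.75 ± 0.37. Cholesterol synthesis genes had a mean of -0.03 ± 0.14 and a median of 0 over 13 genes (adjusted p = 0.85 with limma's camera), with Sc5d at -0.21 ± 0.07 and Msmo1 at 0.27 ± 0.30. Only 4 sex-linked genes were measured, too few for a test, with Kdm5d at 0.23 ± 0.51, Eif2s3y at 0.10 ± 0.22 and Uty at -0.15 ± 0.67. Xist had -0.05 ± 0.82, with 0.59, 0.24 and -0.97 on replicates 1, 2 and 3. None of the 4 kept 1 sign on all 3 arrays, and the sex balance of the samples was not tested.

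Among single genes with the same sign on all 3 arrays, the 10 higher ones of smallest p were of mixed kinds. They included Cartpt (2.87 ± 0.34), a neuropeptide precursor, Tac1 (1.74 ± 0.03), the precursor of substance P, and Gabra5 (2.02 ± 0.14), a GABA-A receptor subunit. Cbln4 (1.99 ± 0.16) and C1ql2 (1.90 ± 0.12) encode secreted synaptic proteins of the C1q family. The others were Ddc, Egfl6 (2.14 ± 0.26), Agpat5 (1.95 ± 0.17), Ssxb1 (1.91 ± 0.11) and the olfactory receptor gene Olfr889 (1.90 ± 0.14). The 10 lower ones were Etv1, Nhlh1, Smarca5-ps, Chil5 (-3.10 ± 0.45), Mrln (-2.62 ± 0.07), Ptpn22 (-2.36 ± 0.26), Crtam (-2.23 ± 0.25), Trmt9b (-1.89 ± 0.07), Sult6b1 (-1.78 ± 0.09) and Ly6d (-1.75 ± 0.13). Cartpt was 7.31-fold higher and Chil5 8.59-fold lower. Each of these 20 genes had an adjusted p of 0.084 (limma's moderated statistic, Benjamini-Hochberg), the smallest over all features, and none passed the threshold of 0.05.

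**Figure D3:**
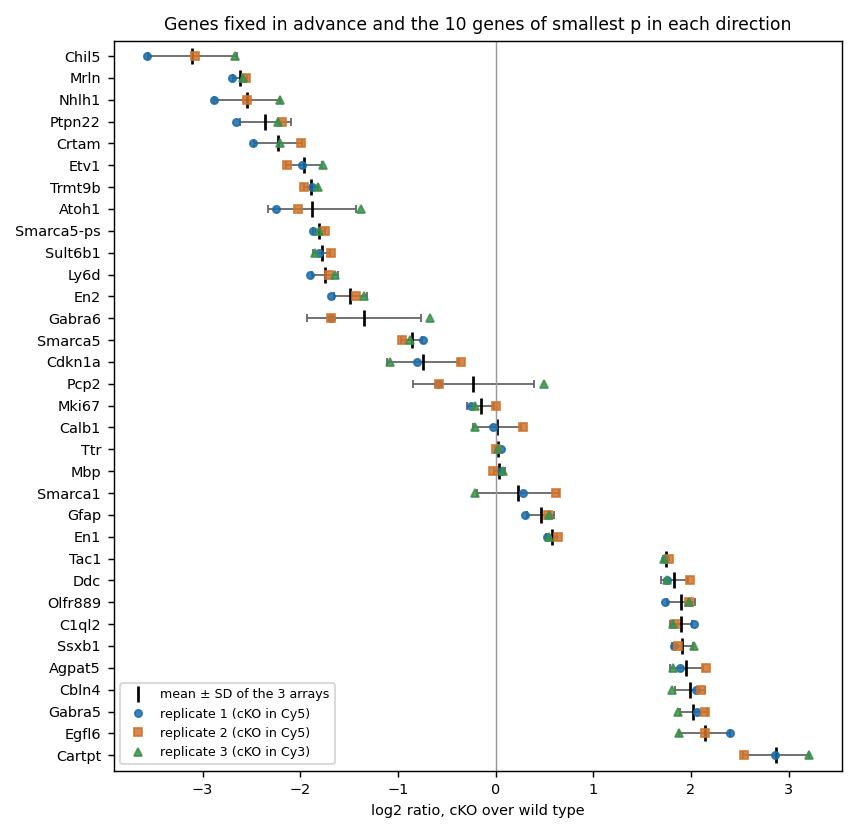
Log2 ratio (cKO over wild type) on each of the 3 arrays, with mean and SD, for the 13 genes fixed in advance and the 10 genes of smallest p in each direction. Pcp2, Calb1, Smarca1, Mki67 and Mbp change sign between arrays, Ttr is at 0 on replicate 2, and the other genes keep 1 sign.

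Over all 28196 features, limma's moderated statistic with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower at adjusted p under 0.05. At an unadjusted p under 0.05 there were 5893 features, 3078 higher and 2815 lower, where 1410 would pass by chance. The one-sample test without moderation called 1 higher and 1 lower feature. These were an unnamed probe at 0.10 and Cerk at -0.06, each with the same value on all 3 arrays and so with no spread at all. An adjusted p under 0.1 in limma gave 592 higher and 476 lower. The sign was the same on all 3 arrays for 43.6% of features, where chance gives 25%. A change of at least 2-fold with the same sign on all arrays was seen for 568 higher and 461 lower features.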

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

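The tests with symbols as on the array, with the marker spots kept, with lists short of their most changed member and with lists short of Smarca5 were chosen only after the data had been seen. In limma, 0 genes were called higher and 0 lower under every alternative except those named here, and 0 and 0 without any single replicate. With the sign of replicate 3 turned, 4 features were lower; all 4, Cd84 among them, had values over 5 in size that changed sign with the dye. The one-sample test without moderation called 1 higher and 1 lower feature, both with equal values on all arrays, and an adjusted p under 0.1 gave 592 higher and 476 lower. The 11 called lists became 1 with the sign turned and 0 with an estimated correlation, for which a simulated list shifted by 1 in all members also had an adjusted p of 0.643. That simulation shifted only 1 list and held no correlation between genes, whereas the granule neuron list had an estimated correlation of 0.172. Estimated correlations were below 0 for the microglial, oligodendrocyte, choroid plexus, brainstem and midbrain, interferon, cell cycle and remodeler lists, from -0.083 to -0.021. These values argue against correlation between genes as the reason why those lists lost their calls. For the other called lists, the simulation does not settle why the calls were lost. Under the other alternatives 9 to 12 lists were called, 9 to 11 without 1 replicate; apart from the sign and the correlation, calls were lost for the remodeler and synapse lists alone. Calls were gained by midbrain-hindbrain patterning with fry (adjusted p = 0.0335) and by red blood cells without replicate 2, the latter tested at the preset correlation alone. Smarca5 stayed below 0 under all alternatives, from -1.28 (1 probe) to -0.28 (sign turned) and from -0.92 to -0.81 without 1 replicate, with adjusted p from 0.0743 to 0.997 in limma.

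No gene was called, so turned directions can be set against calls for lists alone. Lists and named genes whose direction turned are given here, and none of these lists was called as reported. With the sign of replicate 3 turned these were the tests of astrocytes (mean 0.018), linker histones (0.032) and red blood cells (0.22), and Mbp (-0.017), Msmo1 (-0.0067), Hbb-y (0.13), Alas2 (0.21), Kdm5d (-0.05) and Eif2s3y (-0.12). With a dye term they were cholesterol synthesis (-0.0073) and Calb1 (-0.043). The test's direction turned for cholesterol synthesis without moderation (-0.028) and for linker histones with fry (0.045). It turned for p53 targets with each probe tested on its own (-0.0075) and for p53 targets (0.00078) and Purkinje cells (0.033) with symbols as on the array. Without the most changed member it turned for p53 targets (-0.025), Purkinje cells (0.024) and midbrain-hindbrain patterning (0.14). With 1 replicate left out, values ran from -0.069 to 0.054 for cholesterol synthesis, 0.017 to 0.061 for linker histones and 0.015 to 0.088 for Purkinje cells. They ran from -0.12 to 0.13 for Calb1 and from -0.015 to 0.21 for Eif2s3y. Beyond the constructions named, the cause was not tested. No paired analysis was possible because there is 1 group of arrays and each array already pairs a cKO with a wild-type sample. A filter on dim probes was not run because no intensities were used here, and signal over background is unknown.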

Other observations

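The tests of the mean of the second list of midbrain and brainstem genes, of sign assignments, of the neighbours of Smarca5 and of olfactory receptors were chosen before their values were computed, although single genes such as Olfr889 had been seen; all other tests in this part were chosen only after the result was seen. Genes of neuropeptides, the peptide transmitters of neurons, were higher in the cKO as a group. Of 24 measured genes, 22 had a mean above 0 and 21 were above 0 on all 3 arrays, with a list mean of 0.82 ± 0.08 (SD, n = 3). In limma's camera the list was higher with an unadjusted p of 2.51e-10 at the preset correlation and 0.0506 with an estimated correlation. Adjusted over the list alone, 15 genes were higher, among them Trh (1.78 ± 0.46), the thyrotropin-releasing hormone precursor, Nts (1.56 ± 0.17), neurotensin, Gal (1.41 ± 0.59), galanin, and Crh (1.25 ± 0.39). Penk, the enkephalin precursor, had 0.08 ± 0.07, and Avp and Oxt had -0.38 ± 0.21 and -0.21 ± 0.40. Other peptides of the hypothalamus, Pmch (1.11 ± 0.47), Hcrt (0.91 ± 0.22) and Pomc (0.61 ± 0.18), were higher over the list alone. This list was drawn up after Cartpt and Tac1 had been seen among the higher genes, so it is not independent evidence, and 2 of its genes stand on a list fixed in advance and 4 on the second midbrain and brainstem list. That second list was higher in the same arrays, with a mean of 0.94 ± 0.12, and carried-over tissue, weighed below, stays open as a candidate source of part of the neuropeptide rise. Midbrain or brainstem tissue leaves the rise of the hypothalamic peptides Pmch, Hcrt and Pomc unexplained, and a source of that rise was not tested.

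The subunits of the GABA-A receptor, the main inhibitory receptor of the brain, moved apart. The 14 measured subunits had a mean of 0.11 ± 0.07 and were not called as a list (camera, unadjusted p = 0.0943 at the preset correlation). Over the list alone, Gabra3 (0.68 ± 0.10), Gabra5 (2.02 ± 0.14), Gabrb1 (0.67 ± 0.20), Gabrg1 (0.69 ± 0.25) and Gabrg3 (0.87 ± 0.27) were higher. The subunits of mature granule neurons, Gabra6 (-1.34 ± 0.58) and Gabrd (-2.50 ± 0.36), were lower over the list alone. This list was drawn up after Gabra5 and Gabrd had been seen, so it is not independent evidence either. The second midbrain and brainstem list was higher in the same arrays (0.94 ± 0.12), and carried-over tissue stays open as a candidate source of the higher subunits.

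Genes of granule neurons were lower in the cKO. Dye bias would turn the list's sign on the dye-flipped array, where its mean was -0.95 against -1.20 on the other arrays, which argues against it. A loss of all kinds of neurons alike would lower Purkinje genes as much, but the granule list lay below the Purkinje list by a mean difference of -1.18 ± 0.18, which argues against that too. Fewer granule neurons, later maturation and lower expression per cell stay open as untested explanations, any of which may act with the genotype. Carried-over tissue of other regions, weighed below, stays open as a part of it.

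Genes of microglia were higher in the cKO. A lower share of granule cells would raise the genes of all other cell types alike. The microglial list exceeded the endothelial, astrocyte and oligodendrocyte lists on all 3 arrays. The smallest mean difference was 0.54 ± 0.03, from the oligodendrocyte list. Members of the oligodendrocyte list spread wider, from Opalin (1.20 ± 0.17) and Pdgfra (1.01 ± 0.15) to Mbp (0.04 ± 0.05), so list means depend on the markers chosen. The difference argues against an equal rise of all lists, but a lower granule share as a part of the rise stays open. Dye bias is argued against by the mean of 0.89 on the dye-flipped array, against 0.93 on the others. More blood in the tissue is argued against by the adult haemoglobin genes, with a mean of -0.12 ± 0.14. The red blood cell genes Alas2 and Slc4a1 were below 0 on replicates 1 (-2.10 and -1.05) and 3 (-1.49 and -1.67). On replicate 2 they were above 0 (1.24 and 2.37), so more blood on that array stays open. More microglia, or higher expression of these genes in each, may follow from the genotype; this is a hypothesis, and tissue of another region and a difference in litter or rearing were not tested.

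Genes of dopamine and serotonin neurons, whose cell bodies lie mainly outside the cerebellum, were higher in the cKO; Th, Ddc, Slc6a3, Slc6a4, Tph2 and the acetylcholine transporter gene Slc18a3, singled out because they passed, had a mean of 2.46 ± 0.28, while all 13 genes of their list had a mean of 1.09 and a median of 0.23. Tissue of midbrain or brainstem nuclei left on the cKO samples is a candidate source: a second list of 29 such genes, none on a list fixed in advance and 4 on the neuropeptide list, had a mean of 0.94 ± 0.12, with 27 above 0, 22 of them on all 3 arrays (camera, unadjusted p = 2.61e-11 at the preset correlation and 0.0171 with an estimated correlation). Slc18a2 (3.24 ± 0.72), Dbh (2.67 ± 0.66) and Slc5a7 (1.61 ± 0.24) led it, whereas Nr4a2 (-1.07 ± 0.22), Pitx3 (0.04 ± 0.35), Sncg (-0.06 ± 0.04), the cholinergic enzyme gene Chat (0.23 ± 0.14) and the hindbrain Hox genes did not go with it. The p-values of the second list are unadjusted, and on the same unadjusted test with an estimated correlation the microglial list had 0.0166 in camera. On this second list, not picked by its values, dye bias is argued against by the mean of 0.80 on the dye-flipped array, against 1.01 on the others. An equal rise of all other cell types is argued against by a smallest difference of 0.56 ± 0.12 from the endothelial, astrocyte and oligodendrocyte lists. As for microglia, that comparison depends on the markers chosen, and a lower granule share as a part stays open. Expression of these midbrain and brainstem genes within the cKO cerebellum stays open and untested. How many of them wild-type cerebellum expresses was not determined without intensities.

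Of the 4 assignments of signs to the arrays, 1, the real one, called 11 lists and the highest of the others called 2, and 4 assignments are too few for a share under 0.05. Among the 40 measured neighbours of Smarca5, 20 on each side on chromosome 8, 2 (5%) had an unadjusted p under 0.01 against 8.58% of all named genes placed in the gene table (Fisher's exact test, 2-sided p = 0.578), which does not tell whether donor-strain DNA came with the targeted allele. Of 890 olfactory receptor genes, 36 (4.04%, exact 95% interval 2.85% to 5.56%) had an unadjusted p under 0.01, above the 1% of chance and below the 8.58% of named genes. A change of at least 2-fold with the same sign on all arrays was seen for 30 of the 890. Among all 28196 features, 568 higher and 461 lower ones met that criterion, so olfactory receptors met it about as often as features in general. These receptors are made in the nose, so signal unrelated to cerebellar expression is a candidate source for part of the single genes, Olfr889 included. Control genes with at least 60 spots each, 7 in all, had a median SD between spots of 0.339, 0.372 and 0.385 on replicates 1, 2 and 3.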
